A study of Mus musculus with 8 samples.

How the data were processed

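The data are one table of 65956 rows (array transcript clusters) by 8 arrays, 1 array for each group. Microglial RNA from C57BL/6J mice was extracted with TRIzol and a total RNA kit and labelled with biotin through a whole-transcript pico kit, per the labels' protocols. The arrays were Affymetrix mouse whole-transcript arrays, and the submitters' processing notes name Affymetrix Expression Console. The deposited values are intensities on a linear scale, as their range shows, with array medians from 243 to 269 and maxima between 969237 and 999952, above the 65535 of a 16-bit scanner, so they are summarised values and not scanner readings. How probes were summarised and normalized is not given in the sources used here. No detection calls were used, so a dim gene cannot be told from an absent one, and the precision of every value is limited by the number of arrays. Values above the scanner range, between 2.02% and 2.23% of rows on an array, were kept as deposited.

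Gene names came from a table that pairs the array's probe sets with its annotation, updated through RefSeq records of assembly GRCm38.p6. Of the rows, 31216 carried 1 gene symbol, 1534 carried several and were left out, and 33206 were unnamed here. In 827 cases an old symbol was replaced by the current one. This left 30743 genes, of which 364 had several probe sets and were represented by the brightest. Values were analysed as log2(intensity + 16), which understates the change of dim genes, with no further normalization. A gene was tested if it lay above the array's 50th percentile of named probe sets on at least 1 array, which kept 18244 genes, 1010 of them on X and 67 on Y. Genes of multicopy families, pseudogenes and paralogs can share probe sequences, so their values are uncertain.

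Groups were taken from the labels. The label FL, and F/F on the p50 arrays, was taken as the control genotype. Since no group holds more than 1 array, the main test was an additive linear model of state and genotype over all 8 arrays, fitted with limma (lmFit and eBayes), with 3 residual degrees of freedom, a prior SD of 0.16 log2 units and Benjamini-Hochberg adjustment over the genes tested, at an adjusted p of 0.05. A gene whose genotype difference depends on the state counts as spread in this model, and the p-values measure the spread between these arrays. The 5 comparisons were genotype over the 4 states, EAE against naive, iguratimod in EAE against EAE, and p50 EAE against naive and against EAE. Comparisons of 1 array with 1 array were not tested, and genes with a difference of at least 2-fold were counted. The difference between genotypes in the response to EAE or iguratimod was planned as values only. It was also fitted with limma, a choice made after the data were seen, giving the compared states a genotype effect each and letting the other states share 1, which leaves 1 residual degree of freedom. A fit in which only EAE or only iguratimod has a genotype effect of its own leaves 2.

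The 35 gene lists, covering microglial states, immune and metabolic pathways and markers of other cell types, were fixed before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. Lists with at least 3 tested members were described by the median log2 difference, its percentile among 10000 random lists of the same size matched on mean brightness in 20 bins, and the number of members passing over all genes and adjusted over the list alone. A difference below all or above all random lists describes these arrays and is no test. For genotype, the list mean was also put to an exact sign-flip permutation test over the 4 states, two-sided. Of the genes in the lists, 18 belong to more than 1 list.

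Named genes were, for each comparison over several arrays, the 12 higher and 12 lower genes with the same sign in every pair and the largest smallest difference, and for genotype within a state and for the genotype difference of the EAE change the 6 highest and 6 lowest. The brighter group had to lie above the 60th percentile of tested genes. Predicted genes, numbered loci, small RNAs, pseudogenes, chemosensory receptors and antigen receptor segments were counted but not named. From each list, members that passed or had the largest differences were named. The model was tested on simulated data with 100 genes changed by 1 and 100 by 2 log2 units, in which it made 7 false calls among 161 for genotype and 6 among 105 for iguratimod. The simulated noise was normal, independent between genes and drawn from the fitted prior, and a change was the same in every pair. The spread of the real arrays need not be so, and the simulated rates are no measure of power for them.

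Alternatives were no filter, a filter at the 70th percentile (11447 genes), a further quantile normalization, arrays centred on their median, the mean of a gene's probe sets, a trended and robust prior, leaving out each array or a pair of arrays, and a 1.5-fold threshold for single pairs. Those added after the data were seen were log2 without the offset, X and Y genes left out, the iguratimod pair left out for comparisons other than genotype, and list medians without the p50 pair. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.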

Results

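Microglia from mice were profiled on 8 whole-transcript expression arrays, with 1 array in each of 8 groups. The groups crossed 2 genotypes with 4 states. The control genotype carried floxed alleles, and the other, called icKO here after its label, carried a conditional knockout. The deletion was directed at oligodendroglia, whereas the RNA came from microglia, the resident macrophages of the central nervous system. The states were naive, experimental autoimmune encephalomyelitis (EAE, an autoimmune model of multiple sclerosis), EAE with iguratimod (an anti-inflammatory antirheumatic drug), and a further EAE pair whose labels carry the mark p50, the meaning of which the labels do not give. The design text names the naive control array as the reference, and the series title presents the knockout as a model of secondary progressive multiple sclerosis. Median intensity per array ran from 243 to 269. Of 30743 named genes, 18244 were bright enough on at least 1 array to be tested. The genotypes were taken from the labels and were not checked against expression. With 1 array per group, each comparison over several arrays took its spread from how far the genotype and state differences failed to add up, and the number of arrays limits the precision of every value. The labels do not say how many animals stand behind an array.

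In EAE, the medians of the antigen presentation, interferon response and cell cycle lists were higher than in naive microglia in both genotypes. The MHC class II genes H2-Ab1 and H2-Eb1, which present antigen to helper T cells, rose by 5.10 ± 0.56 (SE) and 4.98 ± 0.62 on the log2 scale against naive, with limma adjusted p of 0.0214 and 0.0236. Cxcl9, a chemokine that attracts activated T cells, rose by 5.49 ± 0.86 (adjusted p = 0.0334), and the activating Fc receptor gene Fcgr4 rose by 4.95 ± 0.42 (adjusted p = 0.0168). Mki67, a marker of dividing cells, rose by 3.56 ± 0.17 and had the lowest adjusted p of all genes (0.0136). In all, 678 genes passed the test, 608 of them higher and 70 lower in EAE. Of the 678, 424 belonged to kinds that are not named here, among them predicted genes and ribosomal protein pseudogenes.

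The EAE comparison was next read over the lists of genes fixed in advance. In the MHC class I list, 7 of 11 measured members rose over all genes tested and 10 rose when adjusted over the list alone, with H2-K1 up by 2.82 ± 0.31, H2-D1 by 2.67 ± 0.24 and B2m by 1.16 ± 0.13. In the MHC class II list 7 of 12 rose by both counts, including H2-Aa at 3.62 ± 0.54 and the peptide-loading gene H2-DMb1 at 1.74 ± 0.16. In the interferon response list 7 of 21 rose, and 16 when adjusted over the list alone. Gbp2, an interferon-induced GTPase, rose by 3.03 ± 0.31, and the interferon signalling factor gene Stat2 by 1.99 ± 0.25. The interferon-inducible genes Ifi204, Ifi207 and Ifi211 rose by 4.66 ± 0.62, 4.37 ± 0.66 and 4.28 ± 0.54. In the cell cycle list 6 of 15 rose, and 12 when adjusted over the list alone, with Top2a up by 1.18 ± 0.17 and Ccna2 by 1.07 ± 0.13. Complement genes rose in 5 of 11 cases (9 adjusted over the list alone), with C4b up by 3.39 ± 0.39 and Cfb by 1.68 ± 0.30. Chemokines rose in 4 of 14 cases (8 adjusted over the list alone), including Ccl2, a monocyte attractant, by 2.93 ± 0.52 and Ccl12 by 2.30 ± 0.33. Proinflammatory mediators rose in 4 of 14 cases (8 adjusted over the list alone), among them Casp1, the inflammasome protease, by 1.41 ± 0.17 and Il1rn, which encodes the interleukin 1 receptor antagonist, by 1.63 ± 0.29.

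Genes of the disease-associated microglia signature had a median log2 difference of 1.07 in EAE, and all 20 measured members were higher on average over the genotypes. Lpl was not higher in control (-0.006), nor Trem2 in icKO (-0.37). Only Cst7 (4.22 ± 0.66) and Ctsl (1.28 ± 0.22) passed over all genes, against 12 when adjusted over the list alone. Clec7a, a pattern recognition receptor of that signature, gave 4.82 ± 1.12 with an adjusted p of 0.0836. Phagocytosis and lysosome genes rose in 3 of 20 cases (14 adjusted over the list alone), with Ctsc up by 2.22 ± 0.31. Glycolysis genes rose in 2 of 14 cases (9 adjusted over the list alone), led by the glucose transporter gene Slc2a1 at 1.53 ± 0.24. Oxidative phosphorylation genes rose in 4 of 16 cases (8 adjusted over the list alone), with Cox7a2 up by 1.5 ± 0.22. In the other direction, the homeostatic microglia list had a median log2 difference of -0.40, and 0 of its 19 members passed over all genes, with 2 lower when adjusted over the list alone. Gpr34 of that list gave -1.48 ± 0.28 (adjusted p = 0.0512). Among the genes lower in both genotypes, Upk1b fell by 1.68 ± 0.27, the transcription factor gene Sox4 fell by 1.51 ± 0.19 and the receptor gene Gpr165 fell by 1.56 ± 0.18, while Jun gave -1.93 ± 0.41 (adjusted p = 0.0695).

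Markers of blood leukocytes were compared between EAE and naive as well. Neutrophil markers had a median log2 difference of 3.47, with S100a8 at 5.70 ± 1.38 (adjusted p = 0.0940), S100a9 at 4.13 ± 1.17 (adjusted p = 0.132) and Ngp at 4.99 ± 1.18 (adjusted p = 0.0876). None of the 10 passed over all genes, and 8 passed adjusted over the list alone. Monocyte markers had a median of 1.24, and 2 of 10 rose, Ly6c2 by 4.32 ± 0.40 and Ms4a4c by 2.61 ± 0.38 (9 adjusted over the list alone). With these markers higher, a change within microglia cannot be told from a changed share of leukocytes, here and in the comparisons below. The count of 678 genes rested on every naive and EAE array: without any one of the control naive, icKO naive, control EAE or icKO EAE arrays it was 0, and without either p50 array it was 231. After a further quantile normalization it was 268.

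**Figure D1:**
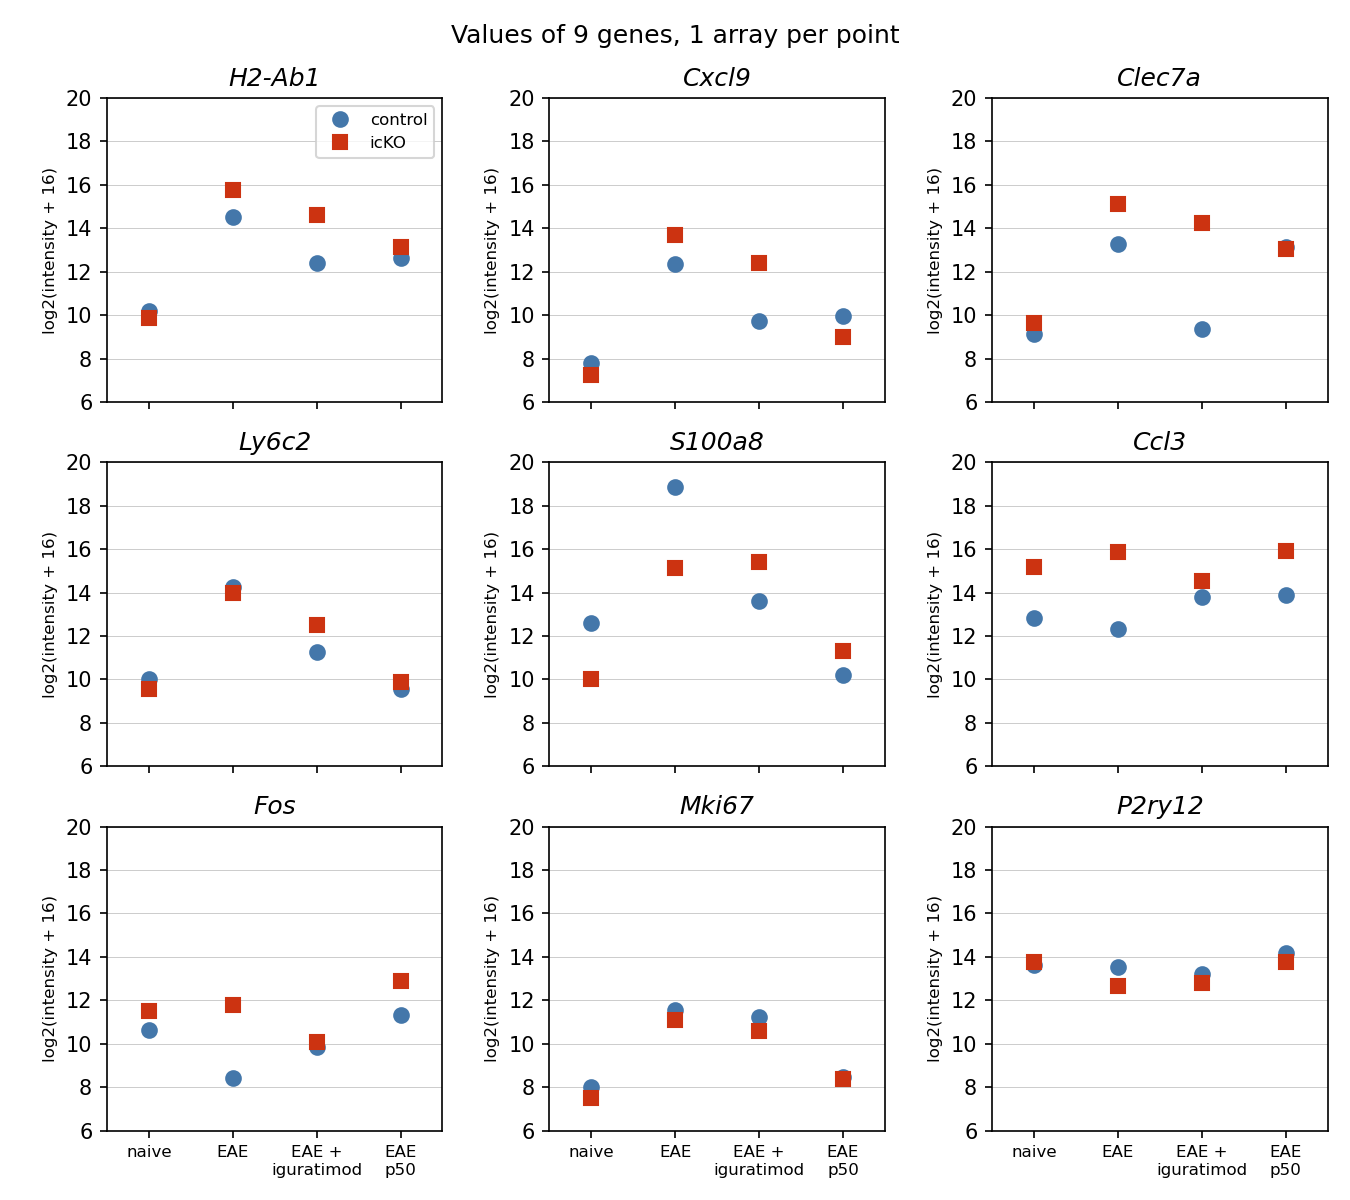
Values of 9 genes on the 8 arrays, as log2 of intensity plus 16 on the vertical axis, by state on the horizontal axis. Each point is 1 array, with blue circles for control and red squares for icKO. H2-Ab1 lay at 10.21 and 9.88 on the naive arrays and at 14.53 and 15.76 on the EAE arrays, and Ccl3 was higher in icKO than in control in each state.

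Across the 4 states, the differences between icKO and control that kept 1 sign in every state included those of chemokine and stress-response genes. Ccl3, which encodes the chemokine MIP-1 alpha, was 4.50-fold brighter in icKO on average, at a log2 difference of 2.17 ± 0.42, and its smallest difference in any state was 0.74. The chemokine genes Ccl2 and Ccl4 gave 1.39 ± 0.37 and 1.13 ± 0.21, the stress-induced transcription factor gene Atf3 gave 1.20 ± 0.31, and the histone gene H1f2 gave 1.19 ± 0.19. Among the 12 genes named in each direction, those lower in icKO had smaller differences, such as -0.50 ± 0.09 for Defb46 and -0.35 ± 0.09 for Crybb1. Of the kinds that are not named here, 99 lower genes ranked above the last of these, against 7 higher ones. None of these passed over all genes: limma called 0 of 18244 genes for genotype, with a lowest adjusted p of 0.862, and 991 genes had an unadjusted p under 0.05. Genes with the same sign in all 4 state pairs made up 12.8% of those tested, against 12.5% by chance. On simulated data, with independent noise and equal changes in every state, the same fit recovered 64% of changes of 1 log2 unit and 90% of changes of 2 log2 units. These rates need not hold for the real arrays.

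The immediate early and dissociation stress list, transcription factors and feedback regulators induced within minutes of stimulation, had a higher median in icKO in 4 of 4 states, although under iguratimod 3 of its 13 members, Jun, Jund and Zfp36, were lower. Its median log2 difference over the states was 0.73, above all 10000 random lists of matched brightness, and 10 of its 13 members passed when adjusted over the list alone, none over all genes. In the chemokine list 3 members and in the NF-kB list 2 members also passed adjusted over the list alone. An exact sign-flip permutation test over the 4 states cannot give a p below 0.13, two-sided, and gave that value for the immediate early list. For chemokines the list median was 0.52 over the states, while in the naive pair its median was -0.08 and its mean 0.20. The disease-associated list had a median of 0.40 and was higher in 3 of 4 states (exact sign-flip permutation p = 0.250).

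Within the naive pair, for which no test was made, Ccl3 was higher in icKO by 2.35, Fosb by 1.64, Rgs1 by 1.61 and Klf6 by 1.55 on the log2 scale. The immediate early list had a median difference of 0.66. Neutrophil genes were lower in icKO already in the naive state, with S100a8 at -2.60, S100a9 at -2.49 and Ngp at -2.33. At least 2-fold differences were counted in 48 genes higher and 300 lower in icKO, and after a further quantile normalization in 123 higher and 216 lower.

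Within the EAE pair, 233 genes were at least 2-fold higher and 103 at least 2-fold lower in icKO. Ccl3 was higher by 3.56, Fosb by 3.42, Fos by 3.38, Dusp1 by 2.92 and Ccl2 by 2.84. The chemokine list had a median difference of 1.12 and the proinflammatory list one of 0.40, both above 100% of random lists, and Il1b lay at 9.77 in control and 11.79 in icKO. Disease-associated genes were higher in icKO by a median of 0.44, and homeostatic genes were lower by a median of -0.41 (below all random lists), with 18 of 19 lower. P2ry12, the purinergic receptor of surveying microglia, lay at 13.52 in control and 12.67 in icKO. Neutrophil genes ran the other way, with a median of -2.63 and all 10 members lower in icKO, among them Retnlg at -4.54, S100a8 at -3.76, Camp at -3.08 and Ltf at -2.97.

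The change from naive to EAE was also compared between the genotypes. With the p50 and iguratimod pairs sharing 1 genotype effect, which leaves 1 residual degree of freedom, limma called 0 genes for this difference (lowest adjusted p = 0.529; 1135 genes at an unadjusted p under 0.05). As values, it was larger in icKO by 2.97 for Cxcl13, a chemokine that attracts B cells, by 2.92 for Arg1, the arginase of alternatively activated macrophages, and by 2.70 for Fn1, which encodes fibronectin. Arg1 went from 7.94 to 11.32 in icKO and from 8.03 to 8.50 in control. It was smaller in icKO for the neutrophil genes Wfdc21 (-3.54), Ltf (-2.69) and Retnlg (-2.38). Other neutrophil genes differed less or the other way: S100a9 rose by 4.28 in control and 3.98 in icKO, and Ngp by 4.81 and 5.16. Homeostatic genes had a median change of -0.04 in control and -0.72 in icKO.

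**Figure D2:**
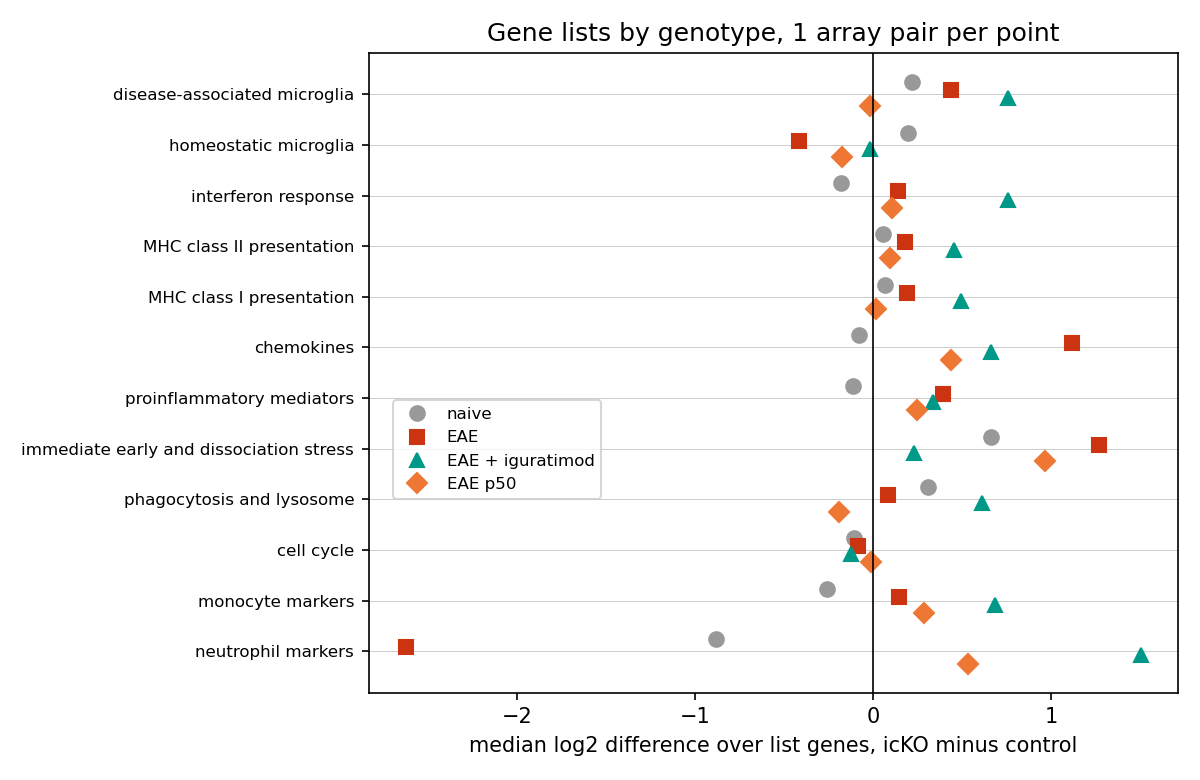
Median log2 difference, icKO minus control, of 12 gene lists, with 1 point for the array pair of each state. The immediate early list was above 0 in each state, and the neutrophil list ran from -2.63 in EAE to 1.5 in EAE with iguratimod.

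Iguratimod was compared with untreated EAE within each genotype. The genes given next were dimmer on the iguratimod array in both genotypes. Averaged over the genotypes, H2-Eb1 gave -2.0 ± 0.62, the cathepsin inhibitor genes Cstb and Cst7 gave -2.21 ± 0.41 and -2.01 ± 0.66, the NADPH oxidase gene Cybb gave -2.14 ± 0.73, Fn1 gave -1.98 ± 0.62 and the GTPase gene Rac2 gave -1.39 ± 0.14. The MHC class II list had a median of -0.51, with 7 of 12 members lower when adjusted over the list alone, and the complement list a median of -0.54, with 6 of 11 lower by the same count. The monocyte marker Ly6c2 gave -2.23 ± 0.40. From EAE to iguratimod the median level of the monocyte list, which holds Fn1, went from 9.55 to 8.52 in control and from 9.45 to 9.22 in icKO. Whether these falls share a source was not tested. No gene passed over all genes: limma called 0, with a lowest adjusted p of 0.508, and 1552 genes had an unadjusted p under 0.05. In the simulated data, with independent noise and equal changes in both pairs, this 2-pair comparison recovered 21% of changes of 1 log2 unit and 78% of changes of 2 log2 units. These rates need not hold for the real arrays. In both genotypes 43 genes were at least 2-fold dimmer and 2 at least 2-fold brighter. Among the brighter genes of the kinds that are named here, Ear14, an eosinophil-associated ribonuclease gene, gave 1.17 ± 0.42 (adjusted p = 0.559). Because the EAE arrays enter this comparison with the opposite sign from the comparison with naive, chance values of those arrays push the differences apart.

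The iguratimod difference was compared between the genotypes in the same way, with the naive and p50 pairs sharing 1 genotype effect, and limma called 0 genes (lowest adjusted p = 0.588; 1525 genes at an unadjusted p under 0.05). The disease-associated list had a median iguratimod change of -0.66 in control and -0.18 in icKO, and Clec7a lay at 13.27 in EAE and 9.38 with iguratimod in control, against 15.14 and 14.24 in icKO. The naive control array had Clec7a at 9.12. Interferon genes had a median change of -0.65 in control and 0.12 in icKO, and neutrophil markers one of -4.08 in control and 0.32 in icKO. The genotype pair under iguratimod held 231 genes at least 2-fold higher and 357 at least 2-fold lower in icKO (329 and 269 after a further quantile normalization). The higher genes were led by Clec7a (4.86), Cxcl13 (4.80), Cybb (3.08), Cxcl9 (2.67), H2-Eb1 (2.51) and Cst7 (2.49), and all 20 disease-associated genes were higher in icKO, by a median of 0.76. Genes lower in icKO included Zfp640 (-1.5) and the lectin receptor gene Clec4a2 (-1.07). Neutrophil markers were higher in icKO in this state by a median of 1.5 and monocyte markers by 0.68.

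The EAE p50 pair was compared with the naive pair and with the EAE pair. Both comparisons also set apart arrays that differ in sex-linked genes, given below, so their differences cannot be ascribed to p50 alone. Against naive, the MHC class I gene H2-D1 rose by 2.03 ± 0.24 (adjusted p = 0.0339), H2-DMb1 by 1.57 ± 0.16 (adjusted p = 0.0181), the antiviral gene Bst2 by 3.01 ± 0.36 (adjusted p = 0.0339), the 1 member of 21 in the interferon list that passed (list median 0.18), and the lipoprotein receptor gene Lrp1 by 1.96 ± 0.17 (adjusted p = 0.0103). Disease-associated genes were higher by a median of 0.69, with 20 of 20 higher on average over the genotypes, 0 passing over all genes and 11 adjusted over the list alone. In icKO alone Trem2 (-0.19) and Cd68 (-0.27) were lower. Clec7a gave 3.69 ± 1.12 (adjusted p = 0.155) and Apoe 2.23 ± 0.55 (adjusted p = 0.114). Against EAE, Ly6c2 fell by 4.41 ± 0.40 (adjusted p = 0.00833), Mki67 fell by 2.89 ± 0.17 (adjusted p = 0.00259) and Gbp2 fell by 2.33 ± 0.31 (adjusted p = 0.0256). In the cell cycle list 6 of 15 fell (10 adjusted over the list alone), and in the interferon list 4 of 21 fell (18 adjusted over the list alone), while Bst2 of that list gave 1.76 ± 0.36 (adjusted p = 0.0709). Immediate early genes rose in 3 of 13 cases against EAE (11 adjusted over the list alone), namely Fosb by 3.75 ± 0.65, Jun by 2.80 ± 0.41 and the heat shock gene Hspa1a by 1.06 ± 0.17. The homeostatic list had a median of 0.79 against EAE, with Tmem119 up by 0.90 ± 0.16 (adjusted p = 0.0485) and 10 of 19 higher when adjusted over the list alone. Neutrophil markers had a median of -3.44 against EAE and monocyte markers one of -1.30.

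The p50 arrays also stood apart from the other 6 in genes of the sex chromosomes. Xist, the RNA that silences an X chromosome in female cells, lay at 15.90 and 16.64 on the p50 arrays and between 7.71 and 8.30 on the others. The Y-linked genes Kdm5d, Eif2s3y and Uty lay between 7.29 and 7.58 on the p50 arrays and between 8.98 and 10.17 on the others. Against naive, 145 genes passed, 67 higher and 78 lower, of which 40 lie on X and 60 on Y (at least 69.0%, since 3 others have no assigned chromosome). Against EAE, 493 passed, 198 higher and 295 lower, of which at least 31.0% lie on X or Y, with 7 unassigned. With X and Y genes left out, which was decided after these values were seen, 0 genes passed against naive and 142 against EAE. The log2 differences stay as they are in that fit, and all 45 called genes not assigned to X or Y kept their sign and an unadjusted p under 0.05 against naive, as did all 340 against EAE. The adjusted p of H2-D1 and of Lrp1 against naive became 0.0976 with 2.03 and 1.96 as before, since fewer genes with low p entered the adjustment. A further quantile normalization gave 299 higher and 117 lower against naive, and 342 higher and 195 lower against EAE. The stricter filter gave 255 higher and 115 lower against naive. Leaving out an array changed the counts too. Against naive they were 71, 64, 68 and 50 without the control naive, icKO naive, control p50 and icKO p50 array, with 18, 2, 22 and 2 of them higher. Without either iguratimod array the count was 221. Against EAE they were 65, 94, 96 and 71 without the control EAE, icKO EAE, control p50 and icKO p50 array, with 2, 28, 40 and 20 of them higher. Without either naive array the count was 296. Within the p50 pair, where the immediate early list had a median of 0.96 in favour of icKO, 53 genes were at least 2-fold higher and 17 at least 2-fold lower in icKO, among them Atf3 (2.31), Ccl3 (2.03) and Fos (1.56).

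**Figure D3:**
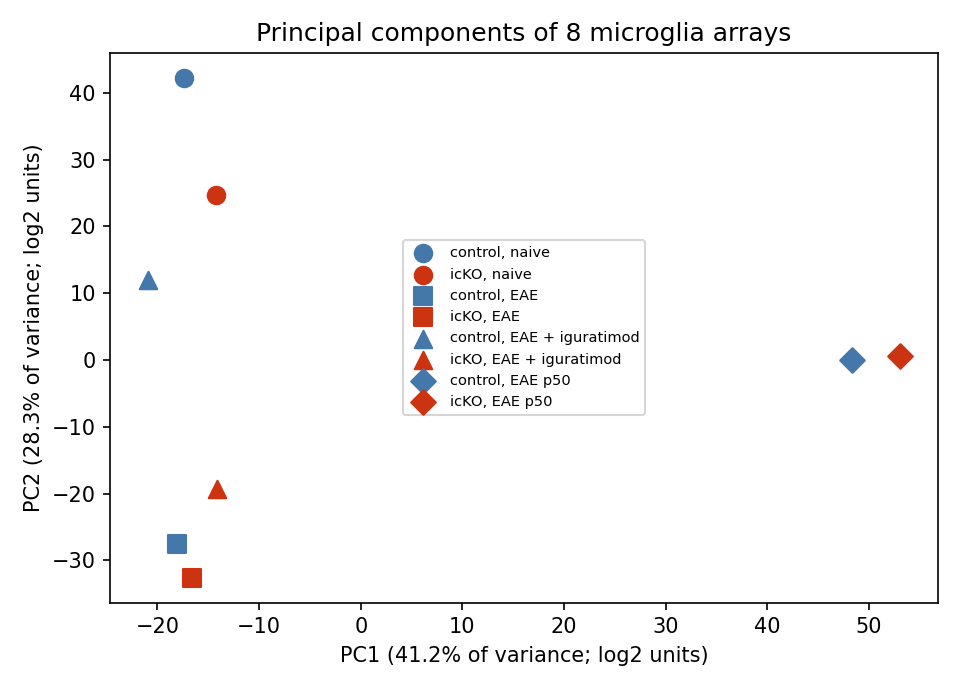
Principal components of the 18244 tested genes on the 8 arrays, with PC1 (41.2% of the variance) on the horizontal and PC2 (28.3%) on the vertical axis. Each symbol is 1 array, coloured by genotype and shaped by state. The p50 arrays lie at 48.3 and 53.0 on PC1 and the other 6 between -20.9 and -14.2, while PC2 runs from the naive arrays (42.2 and 24.7) to the EAE arrays (-27.6 and -32.6).

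Of the named oligodendrocyte markers 1 of 13 was bright enough to be tested, of oligodendrocyte precursor markers 1 of 9, of neuronal markers 0 of 12, of B cell markers 2 of 9, of erythroid markers 2 of 3, of connexins and pannexins 2 of 11 and of T helper cytokines 1 of 9. Among the lists of astrocyte, endothelial, pericyte, T cell, NK cell, dendritic cell, border macrophage and mast cell markers, the median log2 difference between EAE and naive lay between -0.27 and 0.30, and 1 member, Ly6c1 of the endothelial list, rose (1.06 ± 0.19). The T cell gene Cd3e lay at 8.21 on the control EAE array and 9.09 on the icKO EAE array. From naive to EAE, the median level of the immediate early list went from 10.42 to 8.66 in control and from 10.93 to 10.70 in icKO. In control the middle gene was Btg2 in naive and Fosb in EAE, so the gap between these levels is not the median change. Btg2 went from 10.42 to 9.70 in control and Fosb from 11.31 to 8.66. The low level on the control EAE array enters both the genotype difference of that list in EAE and its rise in p50 against EAE. Of the remaining lists, alternative activation had a median of 0.21 in EAE with 2 of 12 risen over all genes (Chil3 by 2.24 ± 0.38, and Il1rn, which the proinflammatory list also holds), NF-kB genes one of 0.27 with 1 of 12 (Icam1, 0.80 ± 0.15), oxidative stress and iron genes one of 0.41 with 1 of 16 (Cybb, 4.52 ± 0.73, also held by the proinflammatory list), cholesterol and lipid handling genes one of 0.31 with 0 of 10, and TGF-beta signalling genes one of 0.07 with 0 of 11.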

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

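Of the tests below, those on neutrophil markers and on the genotype difference of the drug response were chosen after the result was seen. The 7 results listed first were picked out because a list's median lay outside 95% of random lists in opposite directions in the groups compared; the difference of the list medians was not tested. The neutrophil list changed with iguratimod by 0.32 in icKO and -4.08 in control, 4.40 apart. Its genotype difference was 1.5 under iguratimod and -2.63 in EAE, 4.13 apart. Between p50 EAE and naive it changed by 0.99 in icKO and -1.09 in control, 2.09 apart. The immediate early list changed with iguratimod by -0.48 in icKO and 0.47 in control, -0.96 apart. The genotype difference of the interferon list was 0.76 under iguratimod and -0.18 in naive, 0.94 apart, and that of the monocyte list was 0.68 and -0.26, also 0.94 apart. The genotype difference of the phagocytosis and lysosome list was 0.61 under iguratimod and -0.19 in the p50 pair, 0.80 apart.

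Under iguratimod the disease-associated list lay near naive in control (list level 9.95, against 9.48 in naive and 12.08 in EAE) and near EAE in icKO (12.04, against 9.82 and 12.59). Each level is the median over the list on 1 array, so the gaps between levels are not the median changes of its genes. Array scaling is argued against, since the median over the list of the iguratimod change in icKO minus that in control, 0.68 as deposited, was 0.78 after a further quantile normalization. A smaller share of neutrophils in the control iguratimod preparation stays open: in control the neutrophil list changed by -4.08 and the disease-associated list by -0.66, in icKO by 0.32 and -0.18, while against it the control p50 array had a lower neutrophil level than the control iguratimod array (9.21 and 10.72) with a disease-associated level of 11.91, and the order of the icKO arrays differed between the lists, but these values come from other states or the other genotype and do not settle the change within control. Also open are a dependence of the drug response on the genotype, which the design names and for which limma called 0 genes in a fit with 1 residual degree of freedom, and a milder disease or different handling of the animals behind 1 array, for which the labels hold no measure. Over all tested genes the measures differed on where the control iguratimod array lay: 680 genes differed at least 2-fold from naive and 487 from EAE, while the median absolute log2 difference was 0.19 from naive and 0.24 from EAE; the icKO iguratimod array differed at least 2-fold in 403 genes from icKO EAE, 518 from icKO naive and 135 from control EAE, the closest array to it.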

How the results depend on the processing

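The alternatives of log2 without the offset, of X and Y genes left out, of the iguratimod pair left out (except for genotype) and of list medians without the p50 pair were chosen after seeing the data. Genotype and iguratimod gave 0 genes under each alternative run, leaving out each array included. The 678 genes of EAE against naive became 268 after a further quantile normalization and 231 without the p50 pair, and without 1 array they ran from 0 to 605. All 678 kept their direction in every alternative that tested them, but many of these could not change it. The filters, the prior, and leaving out X and Y genes or p50 or iguratimod arrays leave a gene's estimate as it was. Without the p50 pair 226 stayed past the threshold, and fewer arrays leave fewer residual degrees of freedom. Without the iguratimod pair, which leaves as few, 482 stayed, so the lost degrees of freedom alone do not account for the 226. The 145 genes of p50 EAE against naive became 370 under the stricter filter, 416 after quantile normalization, 0 without X and Y genes and 221 without the iguratimod pair, and ran from 50 to 221 without 1 array. The 493 genes of p50 EAE against EAE became 142 without X and Y genes and ran from 65 to 426 without 1 array. The cause of these shifts was not tested, beyond fewer genes or arrays entering the fit. Quantile normalization moved the median over all tested genes by at most 0.104, in the control p50 pair against naive. It also moved the split of genes at least 2-fold higher and lower in p50 against naive in control to 796 and 338 (551 and 428 as deposited), in p50 against EAE in control to 610 and 329 (501 and 451), and in p50 against EAE in icKO to 685 and 574 (585 and 761).

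A 1.5-fold threshold, which by construction admits more genes, gave 1923, 1521, 2543 and 610 genes between genotypes in naive, EAE, iguratimod and p50. It gave 3758 and 3017 for EAE against naive, 2536 and 1835 for iguratimod against EAE, 3426 and 2837 for p50 against naive, and 2600 and 3592 for p50 against EAE, in control and icKO each time. The other 48 recounts at 2-fold stayed within 1.5 times. No list median outside the random range changed sign, with 1026 values within the spread of 0.16 log2 units and 10 beyond it. For named genes no value changed sign, though several of the settings leave the estimate of a gene as it was. With all arrays or without a pair, 1546 values kept their side, 84 called genes fell short of the threshold, 43 passed it newly and 9 untested differences moved by more than that spread; without 1 array 878 kept their side, 318 fell short and 28 passed newly. Fits chosen after seeing the data, in which EAE or iguratimod alone had its own genotype effect, called 0 genes each (1087 and 1504 at an unadjusted p under 0.05 by limma), as did those that set EAE against naive and iguratimod against EAE. Without detection calls, differences among genes near the floor of about 8 log2 units stay uncertain.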

Other observations

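Of the tests in this part, the principal components without X and Y genes were predicted before that result was seen; the others, and the choice of ribosomal and multicopy genes, came after. Of 40 tested ribosomal protein genes, 19 rose in EAE and 21 did not pass. The median log2 difference of the 40 was 0.94, with Rps26 up by 2.23 ± 0.17 (adjusted p = 0.0148) and Rpl35 by 2.41 ± 0.19 (adjusted p = 0.0162). Of 193 ribosomal protein pseudogenes, which share sequence with them, 100 were called higher too. In iguratimod against EAE the median of the 40 ribosomal protein genes was -0.41 with 0 passing, and in p50 EAE against EAE it was -0.67 with 5 lower.

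Some multicopy genes known for expression in testis were bright on arrays of microglia. Orly and Sly of the Y chromosome lay between 13.66 and 15.40 on 6 arrays and between 8.27 and 9.30 on the p50 arrays. The 6 tested Astx genes had medians between 10.70 and 12.57 on those 6 arrays and 9.48 and 9.89 on the p50 arrays, while 17 Btbd35f genes had medians of 10.84 and 10.80 on the p50 arrays against 9.24 to 10.12 on the others. Astx1a, Astx1b and Astx1c had the same value on every array, so the Astx genes are not all separate readings.

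The p50 arrays stood apart from the other 6. Sex-linked genes alone do not account for it: with X and Y genes left out, the first component (35.5% of the variance) no longer set the p50 arrays apart, which the prediction had named as the mark of that cause, but the second did, with 27.1%, a value the prediction had failed to consider, and with 203 genes of unassigned chromosome also left out the second still did, with 26.8%. The sex-linked values are those of female RNA on the p50 arrays and of male RNA on the other 6. Xist was at least 7.60 log2 units higher on each of the p50 arrays than on any other, and Kdm5d, Eif2s3y and Uty were lower. For the differences outside X and Y, sex, a separate batch and whatever p50 stands for cannot be told apart, because each covers the same arrays. The p50 arrays correlated more with each other (Spearman 0.969 over genes, which are not independent replicates) than any other arrays did (0.966 at most), as each of the 3 would give.

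The median of the immediate early list, Ccl3, Ccl4 and Ccl2 were higher in icKO in all 4 states, although Jun, Jund and Zfp36 of that list were lower under iguratimod. Ccl3, Ccl4 and Ccl2 were named by a rule that asks for 1 sign in all 4 states, so for them this follows from the choice. Genes with 1 sign in all 4 made up 12.8% of those tested, against 12.5% by chance. More neutrophils in the icKO preparations are argued against, since the neutrophil list was lower in icKO by -0.88 in naive and -2.63 in EAE, though higher by 1.5 under iguratimod and 0.53 in the p50 pair. Handling stress that differed between preparations stays open. Over the 8 arrays, as deviations from genotype means, Ccl3 followed the immediate early list with r = 0.71 (permutation p = 0.0588, adjusted 0.232 over 5 genes) and rho = 0.74 (permutation p = 0.0458, adjusted 0.189). Without the 2 arrays farthest from the median r was 0.54, so the relation rests in part on those. For Ccl4 r was 0.60 (permutation p = 0.118) and rho 0.57 (permutation p = 0.151). For Ccl2 r was -0.42 (permutation p = 0.304) and rho -0.45 (permutation p = 0.268). The remaining genes of the 5, Cxcl9 and H2-Ab1, gave r of -0.58 and -0.39. The permutations treat the 8 deviations as exchangeable, but the deviations sum to 0 within a genotype and still hold the state differences, so the p-values are approximate. A change with state shared by both would give the same relation, so r cannot decide on handling. Chance differences between single arrays stay open too, as the exact sign-flip permutation test cannot go below the 0.13 it gave. An effect of the genotype, which the design names, was not separated from these and remains a hypothesis.

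Of 35 splits of the 8 arrays into 4 and 4, 32 could be fitted. The real split called 0 genes for genotype, so all 32 gave as many by construction, with a highest of 0 among the others, and this count says nothing about chance. At an unadjusted p under 0.05 the real split gave 991 genes. Of the 8 splits that part the arrays of every state, as the real one does, 4 gave as many, the real one included. The highest other was 1828, and 8 splits are too few for a share under 0.05. Over the 32 splits 12 gave as many, the real one included, the highest being 2840, in splits that part control from icKO in the naive and iguratimod pairs alone. Each split that parts only 2 pairs has a mirror split with the same result, so the 32 are not all distinct fits.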
